A study of Homo sapiens with 2 samples.

How the data were processed

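RNA was sequenced from secondary mammospheres of T47D cells, an established line of luminal, estrogen receptor-positive human breast cancer. Mammospheres are floating clusters of cells grown without attachment to the plate, an assay that enriches for cells able to survive and divide without anchorage. Control and CIC knockdown cells were grown for 7 days as primary mammospheres, passaged, and grown for 7 more days as secondary mammospheres, per the labels' protocols. Total RNA was made into libraries with a strand-specific total RNA kit and sequenced on a NovaSeq instrument. The means of knockdown is not given in the sources used here. The design text speaks of duplicates, but the labels list 1 sample per group and the deposited tables hold 1 column per group. Each group was therefore treated as 1 library, and whether a column pools duplicates is not stated.

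The submitters' processing notes name Trimmomatic, HISAT2 and StringTie and the builds hg38 and GRCh38, without versions. The transcripts carry RefSeq-style identifiers, and positions are given on GRCh38. Per the file headers, each gene and transcript has a read count, an FPKM and a TPM in each library. The deposited read counts are estimated counts: among transcripts with a count, 99.4% in each library lay less than 1 above the product of FPKM, transcript length and a constant per library, within a tolerance of 0.01. That pattern is that of a count computed from coverage and rounded up, so the counts were whole numbers before any step here and needed no further rounding. Because coverage was divided among the transcripts of a gene, an estimated count can move with the division, above all in genes whose transcripts differ much in length or overlap another gene. The FPKM values were made by the authors as fragments per kilobase of transcript, scaled to the fragments of the library. The TPM values were scaled by the authors to a fixed sum per library and came to 999861 in the control column and 999872 in the knockdown column. Deposited lists of assembled transcripts outside annotated genes and of assembled splice variants carry the same units. Transcript lengths were taken as deposited, per the file headers. The transcript table that merges annotated and assembled models was not used here, since its parts were read from the other tables.

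Columns marked KD were taken as the CIC knockdown sample by its title, and columns marked C as the control, the only other sample; 0 columns of per-sample values were left unused for lack of a sample. All 46732 listed genes entered the library totals, which were 47099221 counts for control and 68420805 for CIC knockdown. The tables hold no row of unassigned reads.

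Library sizes were scaled by TMM factors from edgeR 4.0.16 in R 4.3.3, which came to 0.995 for control and 1.00 for CIC knockdown. For each gene, the log2 ratio of CIC knockdown to control was computed from normalised counts (CPM scale) with a prior count of 2, by edgeR's formula. Each ratio has an exact Clopper-Pearson 95% interval, conditional on the summed count. These intervals cover counting error only: they leave out differences between cultures and library preparations, and reads copied by PCR are not independent molecules. Whether the counts are of reads or of fragments is not stated. If both mates of a pair were counted the intervals are too narrow, and the intervals were therefore also computed from halved counts. For a gene with 0 counts in 1 library, the fold was given as a lower bound against a floor of 3 counts in that library. The floor takes the other library's count as exact, and such a bound lies above the lower end of the 95% interval.

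With 1 library per group there is no replicate check, no test and no p-value, and every statement describes these 2 libraries. Genes were counted by a fixed rule of size: a raw count of at least 100 in at least 1 library, a ratio of at least 2-fold either way, and a counting interval on the same side of 1. The named genes were fixed by rule: CIC; the 15 highest and 15 lowest log2 ratios among genes with at least 100 counts whose symbols do not start with LOC, MIR, SNOR, RNU or RN7S; up to 5 members of each gene list with the largest absolute log2 ratio among members with at least 50 counts in 1 library; and ETV1, ETV4 and ETV5. A gene named outside this rule was chosen after its values were seen, and the text says so. Some genes that the rule names are not reported here.

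The 30 gene lists, with 750 entries in all, cover CIC targets and cofactors, immediate early genes, stem cell factors, luminal identity, estrogen receptor targets, basal or myoepithelial genes, mesenchymal factors, epithelial junctions, proteases, the cell cycle, replication-dependent histones, cholesterol and fatty acid synthesis, hypoxia and glycolysis, interferon response, inflammatory genes, the unfolded protein and integrated stress response, p53 targets, Notch, Wnt and Hedgehog genes, receptor tyrosine kinases and ligands, ribosomal proteins, the mitochondrial genome, nuclear oxidative phosphorylation genes, abundant non-coding RNAs, and markers of leukocytes, endothelium and fibroblasts. A member was measured if its counts summed to at least 10 over both libraries. The median log2 ratio of a list was placed as a percentile among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. An interval of the median came from 2000 bootstrap resamples of the members. About 1.5 of 30 lists would fall outside the 2.5th to 97.5th percentiles by chance, and members of a list are not independent. The rule of size, the lists and the naming rule were set before the data were examined.

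The steps were tested on simulated data drawn from the means and library sizes of this comparison, with 200 genes changed. The simulation held counting error only, without differences between cultures or division of reads among transcripts. Its results therefore check the arithmetic of the steps and do not measure errors from those sources. Of the simulated genes, 13682 entered the step, and 100% of those changed 4-fold passed the rule. Of genes changed exactly 2-fold, the threshold itself, 56% passed when higher and 50% when lower, and 0% of unchanged genes passed. The interval held the true ratio in 94% to 100% of the changed genes, depending on the fold, and in 95.2% of unchanged genes. Of 200 unchanged random lists of 20 genes, 4% lay outside the 2.5th to 97.5th percentiles. Of 20 lists shifted by a log2 ratio of 0.3, 100% lay above the 97.5th percentile. The shifted lists were drawn only from genes above a set mean expression, so this share does not cover lists of genes with few counts.

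Alternatives covered scaling by total count, scaling by median-of-ratios size factors from DESeq2 1.42.0 (no other DESeq2 step was used), the authors' TPM and FPKM with a pseudocount of 0.1, prior counts of 0.25 and 10, other count minimums, a 1.5-fold threshold, the gene table that adds assembled transcripts, and protein-coding genes alone. The alternatives planned for replicate columns or for tables without counts had no data to apply to. Alternatives added after the data were seen left structured RNAs out of the scaling, halved the counts behind the intervals, left out readthrough genes with the genes they join, and centred ratios within bins of GC content and transcript length. GC content came from the GENCODE v29 transcripts and was matched for 93.2% of the 13722 genes with at least 100 counts. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used for the other steps and the plots.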

Results

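Gene expression was measured in 2 RNA-seq libraries of T47D secondary mammospheres, 1 from control cells and 1 from CIC knockdown cells. CIC (capicua) is a DNA-binding repressor that ERK signalling inactivates and that keeps ETV4, ETV5 and other genes of the receptor tyrosine kinase pathway low. The comparison asks how the transcriptome of mammospheres differs when CIC is knocked down. The control library held 47099221 counts and the library labelled CIC knockdown 68420805, or 1.45 times as many. Counts were found for 23616 and 24664 genes, of which 12891 and 13664 had at least 100. Protein-coding genes took 78.2% of counts in the control library and 78.6% in the other, and the 7SL RNAs 11.6% in each. The shares were 4.13% and 3.84% for the 7SK RNAs, 0.156% and 0.161% for mitochondrial genes, and 0.196% and 0.209% for ribosomal RNA.

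CIC mRNA was at the same level in both libraries within counting error, while 11 of 18 measured CIC targets were higher in the library labelled CIC knockdown and 2 were lower by their counting intervals. ETV5 was 4.93 times (95% counting interval 4.24 to 5.86) and ETV4 4.62 times (3.71 to 6.0) the control level; both encode ETS transcription factors. Genes of cell division, replication-dependent histones and genes of cholesterol and fatty acid synthesis were higher together, by less than 2-fold each. The medians of the unfolded protein and integrated stress response list, of p53 targets and of immediate early genes were lower than those of matched random lists. There were no replicates, so none of these differences could be set against the spread between cultures.

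CIC (gene 23152, GRCh38 chromosome 19, 42268537 to 42295796) had 607 counts in the control library and 872 in the library labelled CIC knockdown. The ratio was 0.98 (0.882 to 1.09), a log2 ratio of -0.03, and the authors' TPM values were 1.65 and 1.65. From halved counts, which apply if both mates of each pair were counted, the interval was 0.844 to 1.14. The gene has 22 annotated transcripts. The 18 that begin at the upstream start sites, between 42268537 and 42269282, held 558 and 797 counts, a ratio of 0.974 (0.873 to 1.09). The 4 that begin downstream, between 42284573 and 42284665, held 49 and 75 counts, a ratio of 1.04 (0.719 to 1.53). All 24 annotated CIC pseudogenes had 0 counts in both libraries. Since CIC mRNA did not show the loss that the label names, each library is called by its label, and every direction here is between the labels.

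Of the 20 CIC targets in the list, 18 were measured; 11 were higher and 2 lower in the library labelled CIC knockdown by their counting intervals, and 5 overlapped a ratio of 1. Their median log2 ratio was 0.46 (bootstrap interval 0.19 to 1.32), at the 100th percentile of matched random lists, whose central range was -0.15 to 0.18. ETV5 (gene 2119, chromosome 3, 186046314 to 186109089) had 174 and 1268 counts, and ETV4 (gene 2118, chromosome 17, 43527843 to 43546340) had 81 and 557. SPRY4 and SPRED1, feedback inhibitors of the Ras-ERK pathway, had log2 ratios of 1.97 (36 and 214 counts) and 1.04 (578 and 1750 counts). The related SPRED3 stood at 1.2 (33 and 114 counts), and the adaptor gene SHC3 at 1.44 (68 and 275 counts). These 6 targets passed the rule of size. DUSP6, an ERK phosphatase, was higher at 0.50 (706 and 1468 counts) and VGF at 0.69, whereas DUSP5 at -0.23 and EPHA4 at -0.15 were lower; DUSP4 (-0.07) and MAFF (-0.04) overlapped a ratio of 1. CCND1, which encodes cyclin D1, was the most abundant target, with 27500 and 45814 counts and a log2 ratio of 0.18. ETV1 had 0 counts in both libraries. SPRED1, DUSP6, VGF, DUSP5, DUSP4, EPHA4, MAFF and CCND1 fell outside the naming rule and were chosen after their values were seen.

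**Figure D1:**
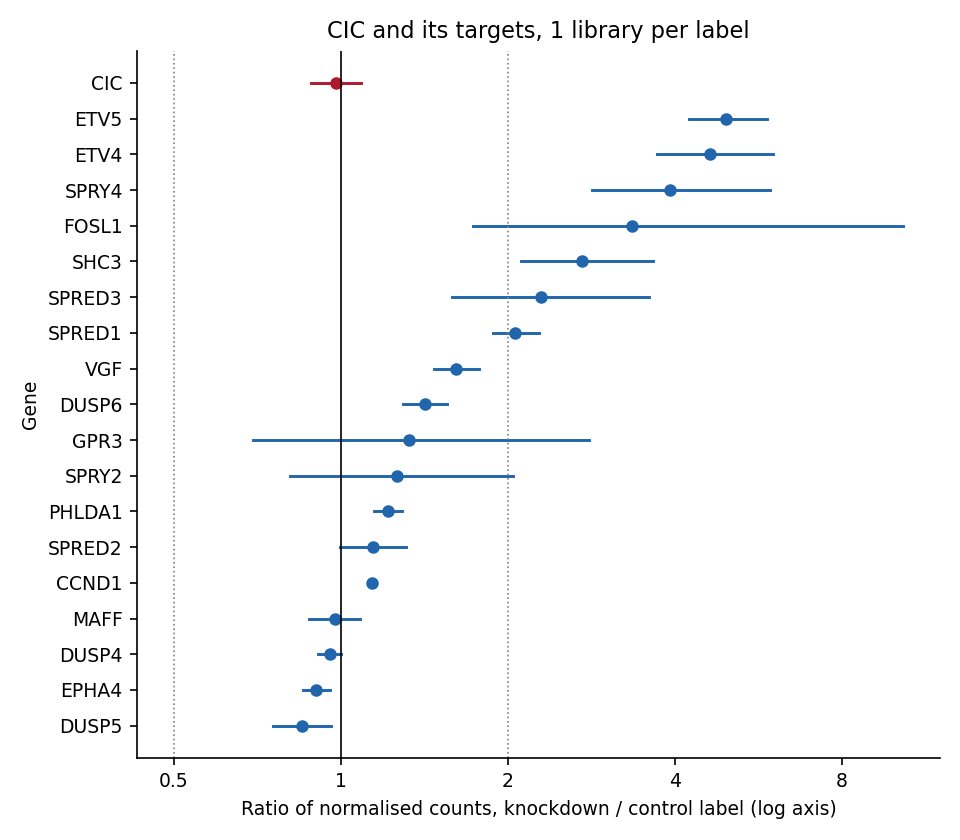
Ratio of normalised counts between the library labelled CIC knockdown and the library labelled control on a log axis (points), with exact 95% counting intervals (bars), for CIC (red) and the 18 measured CIC targets (blue). The solid line marks a ratio of 1 and the dotted lines 2-fold either way; CIC lies at 0.98 and ETV5 and ETV4 at 4.93 and 4.62.

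Of 13722 genes with at least 100 counts in either library, 92.3% lay within 1.5-fold of an equal level. By the rule of size, 161 genes were higher and 132 lower in the library labelled CIC knockdown, of which 135 and 104 were protein-coding. The gene table that adds assembled transcripts gave 219 higher and 225 lower, counted over all its rows, the assembled loci included. Many of the largest ratios belonged to readthrough genes, which join the exons of neighbouring genes and share reads with them: 27 of 82 readthrough genes passed the rule, 18 of them also in the table with assembled transcripts. Folds against a library with 0 counts are lower bounds set against a floor of 3 counts. SERF2-C15ORF63 had 0 and 617 counts, at least 140 times higher, and ARPIN-AP3S2 had 0 and 570, at least 130 times higher. C8orf44-SGK3 was at least 60.9 times higher (0 and 268 counts). Counts of 31 and 631 were found for JMJD7-PLA2G4B, while PLA2G4B, which shares its exons, had 450 and 8. Other readthrough genes were lower: BIVM-ERCC5 had 211 and 0 counts, at least 103 times lower, but a log2 ratio of 0.37 in the table with assembled transcripts. CHKB-CPT1B had 919 and 161 counts, ARPC4-TTLL3 252 and 6, and COMMD3-BMI1 385 and 86. Members of near-identical families stood at the extremes too, such as SEC22B3 (651 and 0 counts, at least 318 times lower), TBC1D3D (115 and 0, at least 56.2 times lower) and LIMS3 (0 and 157, at least 35.7 times higher). The counts of readthrough, overlapping and near-identical genes depend on how reads were divided among them and are uncertain.

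Named genes that are neither readthrough nor near-identical copies also stood at the extremes, although STBD1 among them is joined by a readthrough gene. FUT1, which encodes the fucosyltransferase that makes the H antigen (chromosome 19, 48748011 to 48755390), had 34 and 1509 counts, 28.9 times (21.6 to 43.9) the control level. The long non-coding RNA MIAT had 9 and 169 counts, a ratio of 11 (6.59 to 28.5). KCTD11 (chromosome 17, 7351889 to 7354944) had 934 and 19 counts, a ratio of 0.0156 (0.00832 to 0.0218). MMGT1 had 1473 and 277 counts, a ratio of 0.129 (0.112 to 0.146). The share of counts that moved between transcripts of the gene was 78.8% for KCTD11, 42.2% for MMGT1 and 19.2% for FUT1. The counting intervals leave out any error from that division. STBD1, a glycogen-binding protein, had 1575 and 478 counts but shares reads with the readthrough gene FAM47E-STBD1, named after its values were seen. The log2 ratio was 3.09 for FAM47E-STBD1 against -2.27 for STBD1. On the CPM scale, FAM47E-STBD1 changed by 26.3 and the genes it joins by -27.1. The lower STBD1 count is therefore uncertain, as its reads may have moved to the readthrough gene.

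**Figure D2:**
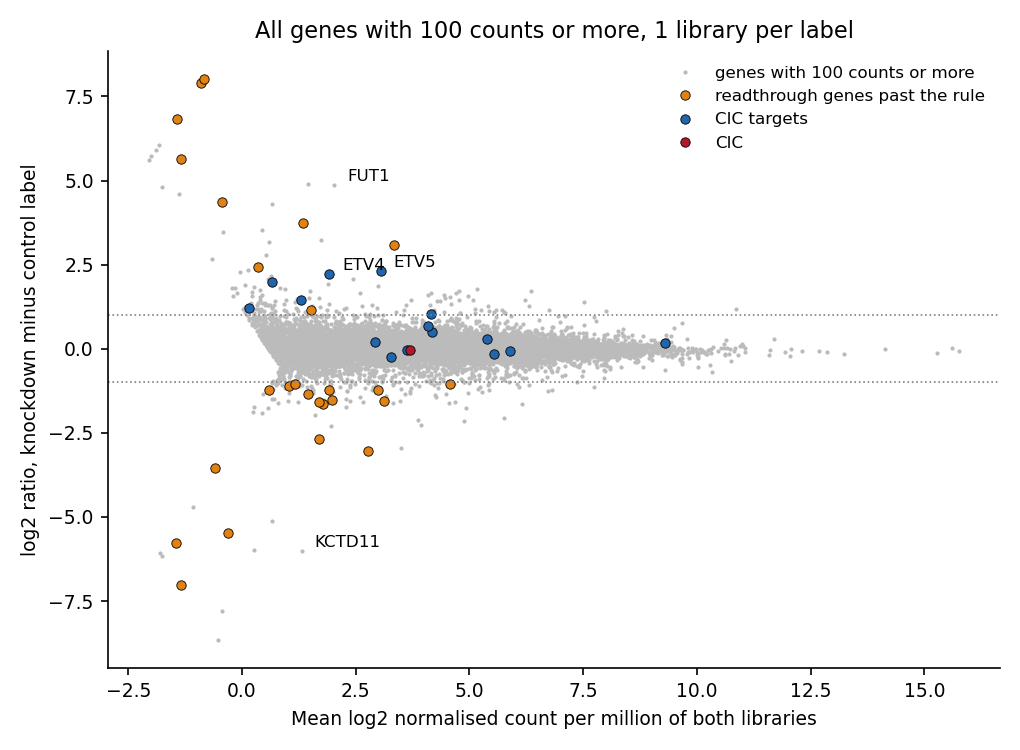
Each grey point is a gene with at least 100 counts in either library, by its mean log2 normalised count, scaled as CPM (x axis), and its log2 ratio between the libraries labelled CIC knockdown and control (y axis), with 2-fold marked by dotted lines. Orange points are the 26 readthrough genes past the rule of size whose joined genes are listed, blue points are CIC targets that reach the same minimum and the red point is CIC, which lies at -0.03.

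Genes of cell division were higher in the library labelled CIC knockdown almost throughout. Of 35 measured genes of the S, G2 and M phases, 34 were higher by their counting intervals, 0 lower, and 0 reached 2-fold. The median log2 ratio was 0.38 (0.33 to 0.44), at the 100th percentile of matched random lists. CCNE1 (cyclin E1) stood at 0.73 with 626 and 1522 counts, the mitotic transcription factor FOXM1 at 0.70 and the mitotic kinase PLK1 at 0.68. The checkpoint kinase BUB1 stood at 0.64 and the centromeric histone CENPA at 0.61. Replication-dependent histones, made during S phase, had a median of 0.26 (0.19 to 0.30), also at the 100th percentile, with 46 of 56 higher and 5 lower by interval. HIST2H3D stood at 0.62 and HIST1H1B at 0.46, with 7242 and 14650 counts.

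Genes of lipid synthesis were higher as well. In the cholesterol synthesis list, 22 of 25 genes were higher and 1 lower by interval. Their median log2 ratio was 0.24 (0.16 to 0.34), at the 100th percentile. HMGCS1, which makes HMG-CoA for the mevalonate pathway, had 6708 and 16178 counts and a ratio of 1.64 (1.60 to 1.69). ACAT2 stood at a log2 ratio of 0.63, NSDHL at 0.46 and SQLE, the squalene epoxidase, at 0.38. In the fatty acid synthesis list, 10 of 17 genes were higher and 3 lower, with a median of 0.29 (0.04 to 0.41) at the 100th percentile. The elongase ELOVL6 stood at 0.47, the desaturase FADS2 at 0.45, malic enzyme ME1 at 0.41 and fatty acid synthase FASN at 0.37.

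Stress response genes went both ways, with more of them lower in the library labelled CIC knockdown. Of 29 measured genes of the unfolded protein and integrated stress response, 19 were lower and 8 higher by interval, with a median of -0.25 (-0.43 to 0.02) at percentile 0 of the random lists. NUPR1 stood at -1.28, the asparagine synthetase ASNS at -1.02 with 2899 and 2090 counts, CHAC1, which degrades glutathione, at -1.01, DDIT3 (CHOP) at -0.65 and the serine synthesis enzyme PHGDH at -0.60. The 8 higher members, named after their values were seen, were SDF2L1 (0.48), CRELD2 (0.23), MANF (0.21), STC2 (0.45), CTH (0.47) and the endoplasmic reticulum chaperones HSPA5 (0.24), PDIA4 (0.13) and HYOU1 (0.12). Of 20 p53 targets, 16 were lower and 1 higher, with a median of -0.17 (-0.21 to -0.13) at percentile 0.02. RRM2B, a ribonucleotide reductase subunit, had 14781 and 9934 counts and a ratio of 0.458 (0.447 to 0.47). SPATA18 stood at -0.58 and the nucleotide excision repair genes XPC and DDB2 at -0.44 and -0.35, while TP53I3 was the member that was higher, at 0.32. Immediate early genes, which respond rapidly to ERK, had a median of -0.18 (-0.26 to -0.03) at percentile 0.32, with 13 of 23 lower and 3 higher. NR4A1 stood at -0.47, IER5 and NR4A2 at -0.40, EGR1 at 0.43 (157 and 312 counts) and CCN2 at 1.18 (30 and 103 counts).

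The genes encoded by the mitochondrial genome had a median of -0.25 (-0.41 to -0.07) at percentile 0.09, with 7 of 13 lower and 2 higher. ND2 stood at -1.0 (1163 and 850 counts), ND1 at -0.61, ND3 at -0.50, ND4 at -0.41 and CYTB at -0.36. The higher members were COX1 (30084 and 46851 counts) at 0.09 and COX3 (30546 and 47468 counts) at 0.08, named after their values were seen; they held most of the counts of the list, and mitochondrial genes together took 0.156% and 0.161% of all counts. Nuclear genes of oxidative phosphorylation lay inside the random range, with a median of 0.04 at percentile 90.7 and examples from NDUFB9 at 0.26 to NDUFA1 at -0.15. Ribosomal protein genes had a median of -0.08 (-0.11 to -0.05) at percentile 0.14, and 52 of 73 were lower by interval and 7 higher. RPL6 stood at -0.28, RPL32 at 0.39 and RPS16 at 0.49.

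Stem cell factors and breast stem cell markers went both ways: 11 of 23 measured members were higher and 6 lower, and the median of 0.08 (-0.13 to 0.39) lay at percentile 88.7. DNER stood at 1.08 (32 and 102 counts), the intermediate filament gene NES (nestin) at 0.83 (797 and 2073 counts), and ALDH1A3, an aldehyde dehydrogenase, at 0.65 (95 and 220 counts). The surface markers CD24 and CD44 were lower, at -0.55 (58763 and 58986 counts) and -0.47 (738 and 781 counts). SOX2, named after its value was seen, was a highly counted pluripotency factor in both libraries, with 3403 and 6088 counts and a log2 ratio of 0.29. Some members with too few counts for the naming rule, also named after their values were seen, had larger absolute log2 ratios than DNER. LIN28A (0 and 41 counts) and LIN28B (0 and 14 counts) were higher by interval, at 4.19 and 2.78. POU5F1 (20 and 12 counts) and PROM1 (12 and 6 counts) were lower by interval, at -1.14 and -1.25.

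Luminal identity genes lay at percentile 50 of the random lists, with 6 of 20 higher and 9 lower, and the sign of their median varied among the alternatives. The progesterone receptor gene PGR had 1141 and 3466 counts, a ratio of 2.07 (1.94 to 2.22), and AGR2, a disulfide isomerase, stood at 0.76 and AGR3 at 0.53. ELF5, a factor of the luminal progenitor lineage, stood at -0.44, and MUC1 at -0.62 in counts (288 and 273) but at 0.10 in TPM. Estrogen receptor targets, 4 of which are also in other lists, had a median of 0.12 (0.03 to 0.27) at percentile 98.0, with 14 of 23 higher and 4 lower. This list lay inside the random range in 4 of 12 alternatives, at percentiles from 87.8 in FPKM to 97.0. Beside PGR, PDZK1 stood at 0.75, KCNK5 at 0.74, ADORA1 at 0.69 (40 and 96 counts) and TFF3, a secreted trefoil peptide, at -0.82. Receptor tyrosine kinases and ligands had a median of 0.11 at percentile 96.0, above the random range in 3 of 12 alternatives (98.35 to 98.7), with 12 of 22 higher and 2 lower. EGF stood at 0.99 (110 and 323 counts), FGFR4 at 0.77, IGF1R at 0.65, KIT at 0.56 (29 and 64 counts) and IGFBP5 at -0.56.

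Notch genes had a median of 0.14 at percentile 94.7, with HEY2 at 0.71 and HEY1 at 0.46, and DLL4 (0.32), NOTCH3 (0.19) and NRARP (0.17) nearer to equal levels. Wnt targets and feedback genes had a median of 0.16 at percentile 91.5, with the R-spondin receptor LGR4 at -1.13 (2589 and 1739 counts), TNFRSF19 at 0.48 and APCDD1 at -0.39. The Hedgehog list held 6 measured members, lay at percentile 46.8 and included SHH at 0.27 and PTCH1 at -0.03. CIC cofactors had a median of 0.11 at percentile 91.9, with 8 of 11 higher and 1 lower. ATXN1, the ataxin that binds CIC, stood at 0.65 (2575 and 5942 counts), ARID1A at 0.27 and SMARCA2 at -0.18.

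Lists of cell shape and invasion lay inside the random range. Mesenchymal and EMT factors had a median of 0.11 at percentile 73.0, with TGFBI at 0.52, SNAI1 at 0.50 (55 and 115 counts) and FN1, fibronectin, at -0.36. Epithelial junction genes had a median of 0.05 at percentile 82.4, which turned negative after GC and length centring. PKP1 stood at -0.67, CLDN1 at 0.59 (43 and 96 counts) and DSP at -0.25. Proteases and invasion genes had a median of -0.09 at percentile 7.74, with TIMP3 at -0.76. Basal or myoepithelial genes had a median of -0.04 at percentile 30.4. KRT6A stood at -1.88 (105 and 40 counts), CAV1 at -0.91, KRT16 at -0.54 (71 and 71 counts) and MYLK at 0.68 (63 and 149 counts).

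Inflammatory and NF-kB targets had a median of 0.13 at percentile 83.8, which was negative under some alternatives. The calprotectin genes S100A8 and S100A9 stood at -2.15 (66 and 20 counts) and -1.44 (462 and 248 counts), BIRC3 at -0.81, TNFAIP3 at -0.45 and TNFAIP2 at 0.41. Interferon response genes lay at percentile 16.7 with a median of -0.04; CMPK2 stood at 1.5 (19 and 83 counts), IFIT3 at 0.51, OAS2 at -0.55 and BST2 at -0.45. Hypoxia and glycolysis genes had a median of -0.07 at percentile 3.15, with 17 of 32 lower and 7 higher, and lay below the random range in 3 of 12 alternatives, at percentile 0.35 after GC and length centring. SLC2A3, a glucose transporter, stood at -0.41 (63 and 69 counts), PFKFB3 at -0.40 and the lactate exporter SLC16A3 at 0.37. Abundant non-coding RNAs had a median of -0.06 at percentile 21.9. MALAT1 stood at -0.48 and RN7SK at -0.12, and NEAT1 at 1.2 in counts but at -0.37 in TPM.

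Markers of other cell types were few and mostly low. Leukocyte markers had 3 of 14 measured, at percentile 57.6, with CD68 at 89 and 146 counts. Endothelial markers had 6 of 10 measured and a median of 1.14 (-0.12 to 2.39) at percentile 99.9. With genes at 0 counts set at their bound the median was 0.97, and in FPKM the percentile was 90.5. Only EMCN, at 197 and 252 counts and a log2 ratio of -0.20, exceeded 50 counts in either library, and the other 5 measured markers had 42 or fewer. Fibroblast markers had 6 of 12 measured and a median of -0.11 at percentile 23.9. Within them the collagen genes COL3A1, at 1.27 (2384 and 8415 counts), and COL1A1, at 0.96 (58 and 168 counts), were higher, and the proteoglycan LUM, at -0.90 (550 and 432 counts), was lower.

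**Figure D3:**
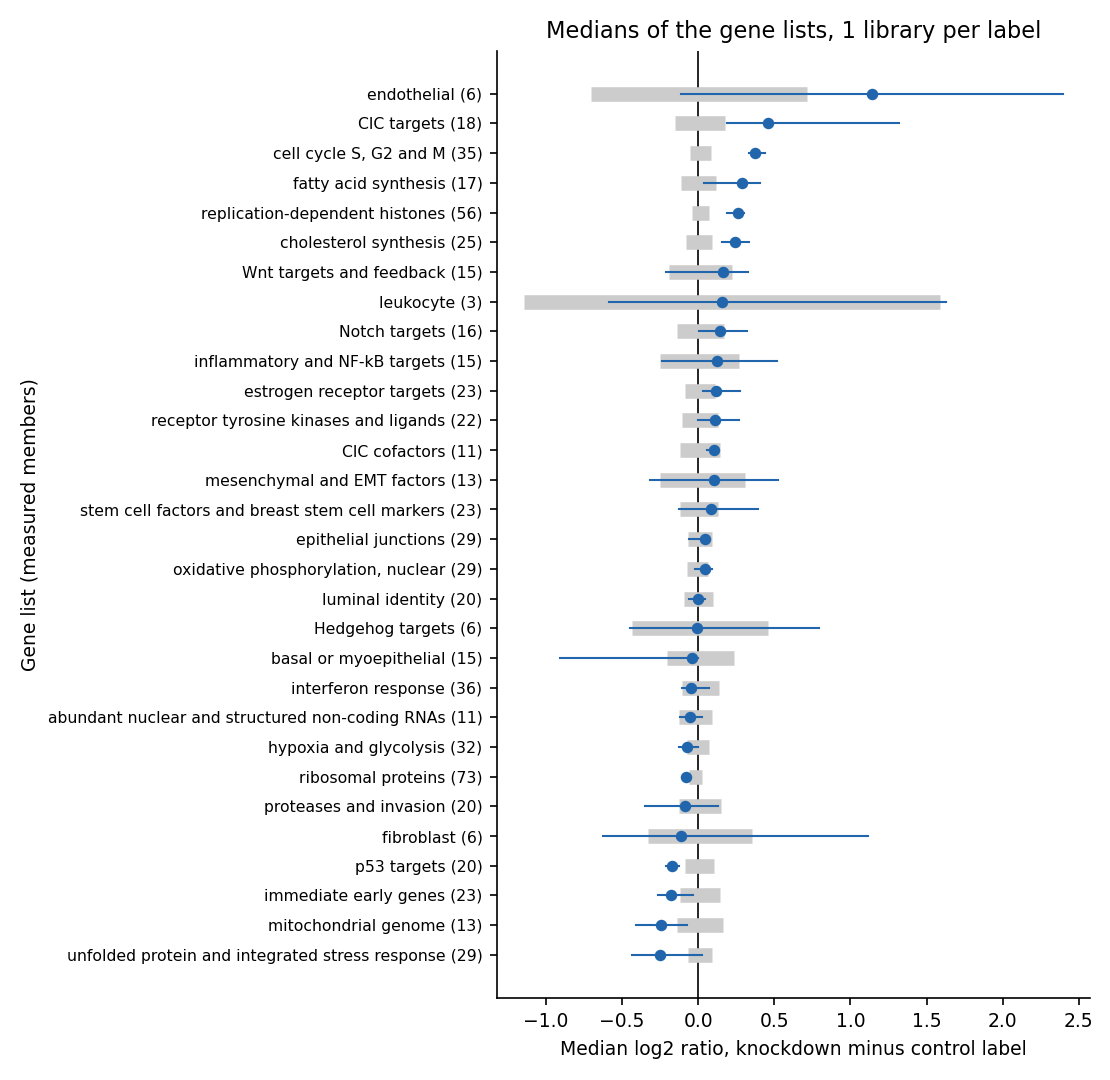
Median log2 ratio between the libraries labelled CIC knockdown and control (x axis) of each of the 30 gene lists (y axis, with the number of measured members). Points are medians, blue lines bootstrap 95% intervals over the members, and grey bars the central 95% of 10000 random lists matched on expression; cell cycle genes lie at 0.38 and the unfolded protein and integrated stress response list at -0.25, both outside their grey bars.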

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

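No explanation was tested for these results, and the 3 loci described singly were chosen after their values were seen. The authors' list of transcripts assembled outside annotated genes held 740 loci, of which 343 had at least 100 counts. These loci enter the comparisons above only through the gene table that adds assembled transcripts. These loci drew attention because some had signal outside the main measurement above the control level. Of the 343, 6 were at least 2-fold higher in the library labelled CIC knockdown by the rule of size, and 9 were lower. Among the 13722 annotated genes with at least 100 counts, 161 were higher and 132 lower. The 3 loci described singly are all among the 6 higher. All assembled loci together took 0.61% of the counts of the gene table that adds assembled transcripts in the control library and 0.57% in the library labelled CIC knockdown.

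The locus with the highest ratio among these 6 lies on GRCh38 chromosome 11, 127940272 to 127941810, and had 0 counts in the control library and 1209 in the library labelled CIC knockdown, at least 278 times higher. It holds 2 assembled transcripts on the minus strand and overlaps the RefSeq pseudogene DNAJB6P1, so its reads could not be separated with certainty from those of near-identical genes. The nearest protein-coding genes are KIRREL3, 937 kb to the left, and ETS1, 517 kb to the right.

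A locus on chromosome 22, 16748737 to 16754231, between CCT8L2 (156 kb) and XKR3 (29.2 kb), had 139 and 606 counts, a ratio of 2.98 (2.49 to 3.64). A locus on chromosome 8, 121140056 to 121145535, which overlaps the RefSeq gene LOC124902010 and lies between SNTB1 (328 kb) and HAS2 (467 kb), had 94 and 415 counts, a ratio of 3.01 (2.43 to 3.85).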

How the results depend on the processing

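The alternatives that leave structured RNAs out of the scaling, halve the counts behind the intervals, leave out readthrough genes or centre on GC content and length were chosen after the results were seen. CIC stayed near equal levels in 9 alternatives (log2 ratio -0.05 to -0.00), and the CIC target median stayed between 0.37 and 0.50 in 12. In 12 alternatives each, the cell cycle, histone, cholesterol and fatty acid lists lay at percentile 100, the unfolded protein and integrated stress response list at 0, and p53 targets between 0 and 0.4. Of 30 lists, 24 kept their side of the random range in the alternatives run; estrogen receptor targets changed it in 4, hypoxia, receptor tyrosine kinase and endothelial genes in 3 each, and stem cell and Notch genes in 1 each. Of 358 list medians, 349 stayed inside their bootstrap intervals, and 21 of 30 gene counts stayed within 1.5 times the reported count. Of 1518 values of single named genes, 1374 stayed inside the counting interval, 138 moved out of it and 6 turned to the other direction. A turn was counted only where the counting interval excluded a ratio of 1, so changes of sign in other genes are not among the 6.

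In the authors' TPM, medians moved to 0.13 for CIC cofactors, 0.088 for epithelial junctions, 0.30 for histones, -0.10 for p53 targets, -0.039 for ribosomal proteins and 0.092 for nuclear oxidative phosphorylation. The p53 median was -0.12 in FPKM and -0.22 after GC and length centring. NEAT1 turned to -0.37 in TPM, -0.39 in FPKM and -0.13 in the table with assembled transcripts, MUC1 to 0.10 in TPM and 0.083 in FPKM, and BIVM-ERCC5 to 0.37 in the table with assembled transcripts. TPM and FPKM divide by transcript length. The counts of NEAT1 and MUC1 were split in other proportions among transcripts of unlike length in each library. For the table with assembled transcripts the cause was not tested. Endothelial markers turned to -0.20 with at least 100 counts per member, which left 1 marker. Counts of higher and lower genes were 1107 and 1181 with no minimum, 964 and 813 from 10 counts, 62 and 56 from 500 counts, and 587 and 470 at 1.5-fold, by construction of each rule. The table with assembled transcripts gave 225 lower genes, for a cause not tested, and 18 of 27 readthrough genes (66.7%) and 238 of 266 other genes (89.5%) past the rule passed it there too. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. Depth limits genes of few counts: SPRED3, with 33 and 114, has a ratio anywhere from 1.59 to 3.58.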

Other observations

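The tests of label exchange, of too few CIC reads, of an ERK-wide rise, of division of reads among the transcripts of readthrough genes and of a difference between single cultures were chosen only after the result was seen, as was the stricter gene selection described first; the tests on the genes that readthrough genes join and on GC content were added after the other results but set before their own.

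Protein-coding genes with at least 500 counts, no readthrough partner, no overlapping exon on the same strand and a ratio past the rule in both gene tables numbered 35 higher and 32 lower in the library labelled CIC knockdown. Among the higher were CP (ceruloplasmin, a copper-carrying ferroxidase), with 195 and 1047 counts and a ratio of 3.64 (3.14 to 4.29), and NDUFA5, a subunit of respiratory complex I, with 2127 and 10263 counts and a ratio of 3.29 (3.14 to 3.45). The mitochondrial ribosomal protein genes MRPS27 and MRPL10 had log2 ratios of 1.51 and 1.41. DCTPP1, which hydrolyses dCTP, stood at 1.56 with 855 and 3696 counts. MGP (matrix Gla protein, an inhibitor of calcification) stood at 1.45 with 370 and 1485 counts, and the intestinal and urothelial keratin KRT20 at 1.41.

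Among the lower were HSDL1, with 5133 and 1821 counts and a ratio of 0.242 (0.229 to 0.255), and LSM4, a protein of the U6 small nuclear RNA complex, with 5906 and 2753 counts and a ratio of 0.318 (0.304 to 0.333). CYP4B1, a cytochrome P450, stood at -1.62 and the endosomal GTPase gene RAB35 at -1.30. In 66 of these genes with several transcripts, a median of 31.7% of the counts moved between transcripts of the gene, against 14.4% in 8645 genes at large. The share was 0.18% for DCTPP1 and 0.966% for LSM4, but 86.5% for HSDL1.

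CIC mRNA was no lower in the library labelled CIC knockdown while 11 of 18 of its targets were higher. Exchanged labels with CIC mRNA lowered by 50% or more would put the CIC ratio at 2 or above, but its upper bound was 1.14 even from halved counts. If the targets followed CIC alone, any exchange would also need them to be lower, whereas 6 were higher and 0 lower by the rule of size. The targets may have changed by another route, so they cannot by themselves decide the labels. Too few reads to see a loss of 50% is argued against by the lower bound of the CIC ratio, 0.844 from halved counts. A general rise of the immediate early genes is argued against by their median, at percentile 0.32. These genes respond rapidly, so their level in mammospheres grown for days cannot decide whether ERK activity was higher. A rise of ERK activity stays open. Lower CIC protein with recovered or unaltered mRNA, or a route to the targets that bypasses CIC, may each account for the pattern, and no data here test them.

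Readthrough genes passed the rule of size in 27 of 82 cases (32.9%). Reads moving between a readthrough gene and the genes it joins could give such ratios: in 18 of 26 past the rule (69.2%, interval 48.2% to 85.7%) the joined genes changed the opposite way, against 51.0% of 51 within the rule. The interval includes an even split, so this stays open. Of readthrough genes with 1 transcript, 36.5% (19 of 52, interval 23.6% to 51.0%) passed the rule against 2.03% of other genes with 1 transcript. Division of reads among the transcripts of a gene cannot apply to these by definition, so their share does not test it. Such division stays open for readthrough genes with several transcripts, of which 26.7% (8 of 30) passed. Neither share bears on division of reads between overlapping genes. A true difference in readthrough transcription between the cultures cannot be told apart from reads moving to the joined genes with so few readthrough genes, and was not tested.

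The gene lists outside the random range might follow a trend with GC content or length, since the median log2 ratio went from -0.01 in the tenth of genes with the lowest GC content to 0.09 in the highest. After centring on both, the medians of the cell cycle, histone and cholesterol lists still lay at percentile 100, and those of the unfolded protein and integrated stress response and p53 lists at percentile 0, which argues against that trend as the whole cause; the p53 median went from -0.17 to -0.22. With 1 library per group, a difference between single cultures that does not come from CIC, such as density or time since feeding, cannot be told apart from an effect of the knockdown.

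NEAT1 had 22904 counts on its short and 34509 on its long transcript in the control library, against 22 and 192771 in the library labelled CIC knockdown, and MUC1 had 282 of 288 counts on a transcript that held 14 of 273 in the library labelled CIC knockdown. The short NEAT1 transcript lies within the span of the long one, and the MUC1 transcripts overlap each other. These counts therefore depend on how reads were divided, and a change between transcripts cannot be read from them.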
